A study of Mus musculus with 18 samples.

How the data were processed

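Total RNA from whole spinal cords of SMNΔ7 mice was sequenced after ribosomal RNA removal with a stranded library kit. The SMNΔ7 line models spinal muscular atrophy (SMA): affected pups lack the mouse gene Smn1 and carry human SMN transgenes, and heterozygous mice served as controls. Per the labels, 18 libraries fell into 6 groups of 3, with SMA and control cords at P2, P6 and P10 (postnatal days 2, 6 and 10).

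Per the labels, the authors used Bowtie2 2.2.4, TopHat2 2.1.1, Picard, FastQC, Cufflinks 2.2.1 and Cuffdiff on the mouse build GRCm38; the annotation release, the strand setting and the normalization method were not stated. The deposited tables hold 1 value per group and gene locus, in which the libraries are already combined, so values per library were not analysed here. The authors' unit of expression is FPKM (fragments per kilobase of transcript, scaled to the depth), given with the lower and upper bounds of a model interval in FPKM. A companion table as deposited by the authors holds expected counts, the fragments that Cuffdiff estimated per gene and group, with a model variance in squared fragments. The counts were not whole and their totals were near equal, at 6881671 to 7386338 fragments per group, so they describe a scaled level and not a sum of libraries. Every group value is therefore the authors' value, without a replicate number or standard deviation of its own.

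Of 58570 gene loci, 46527 carried 1 gene symbol, 1508 joined several symbols and 10535 had none; 23 symbols had been turned into dates, as a spreadsheet does, and were left so, so these genes were not named. Symbols were looked up in GENCODE M21, on the same build, for gene type, identifier and coordinates. Of 20009 protein-coding loci matched by symbol, 99.9% overlapped the annotated gene.

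The median distance from the FPKM to the upper bound of its interval was 72.5% to 74.8% of the FPKM for genes at FPKM 1 or more, and 48.7% to 51.1% at FPKM 20 or more. This distance is the only measure of spread that the tables hold. It was 2.17 to 2.20 times the relative standard deviation of the count, and it was read as a 95% interval. Groups were compared by a two-sided z test of the log ratio of FPKM, with a standard error from the distance of the upper bound to the FPKM divided by 1.96. Genes tested had FPKM 1 or more in at least 1 of the compared groups, FPKM above 0 in each and an OK status from Cuffdiff. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The z values were narrower than a standard normal, with a robust standard deviation of 0.262 to 0.47, so the test called few genes. Comparisons were SMA against control at each age, P10 against P2 within each genotype, P6 against P2 in control, and the change from P2 to P10 of the SMA against control difference.

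A model across ages was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the 6 group values, with age as a factor and genotype as the effect, moderated with a trend; it leaves 2 residual degrees of freedom and treats the 3 ages as replicates of the genotype difference. For 38 of 39 gene lists, camera with a preset correlation of 0.01, camera with an estimated correlation, and fry were run on this fit and adjusted over the lists. The median difference of each list at each age was set beside 10000 random lists of the same size matched on mean expression in 20 bins. Of the mitochondrially encoded list only mt-Nd6 was measured as a locus of its own, so that list was not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

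The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were 11 chosen in advance (Smn1, Cdkn1a, Chodl, Chat, Mbp, Gfap, Aif1, Mki67, Snap25, Fzr1 and Cdc20), the called genes with the greatest log2 ratio in each direction, the 5 with the smallest p in a direction with no call, and the called members or the 2 most abundant members of each list. Predicted genes, clone names, microRNAs, small nucleolar RNAs, symbols that begin with Rn, pseudogenes, unnamed loci and joined loci were counted but not named under this rule; other small RNAs were not excluded. Rnu12, a called member of a list, falls under that exclusion and was named after its value was seen. Aif1 was joined with Lst1 and had no value of its own. Some genes that the rule names are left out of the text, though the counts include them. Any other gene named was chosen after its values were seen.

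Developmental position was the distance of a group from control P2 divided by that of control P10, as a median over protein-coding genes at FPKM 5 or more; 100 simulations with no change drew values with the spread between SMA and control at P6. Both tests were tested on simulated data. With the deposited intervals, the z test at a single age recovered 0% to 4% of genes changed 2-fold, 30% to 42% of those changed 4-fold, 58% to 66% at 8-fold and 68% to 84% at 16-fold; for P10 against P2 in control the 16-fold share was 60%. The test of a change of the difference recovered 14% at 4-fold and 71% at 16-fold. The limma fit recovered 93% of genes changed 2-fold and 100% at 4-fold, with 27 false calls among 220. These false calls were a larger share than the adjusted p threshold allows. In the real fit Lars2, with a difference of about 2-fold across ages, was not called. The simulated recovery of the limma fit therefore cannot be taken as the recovery in the real data. The same holds for the z test, whose simulated noise was as wide as the deposited interval, while the real z values were narrower. A minimum share first required of the z test at 16-fold was lowered after the 60% result was seen.

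Alternatives tried were no filter on low values, a filter at FPKM 5, z tests from the counts and their variances, a fold of at least 1.5, log ratios re-centred on the median gene, intervals that do not overlap as the call rule, pseudocounts of 0.1 and 5, quantile normalization, leaving out each age, and no variance trend. With 1 value per group, edgeR, DESeq2, a replicate block and leaving out single libraries could not be applied. Intervals and floors cover the authors' model and counting error only. A floor of 3 fragments in the group was used where an SMA value was at or near 0.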

Results

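Spinal cord transcriptomes of SMA and control mice were compared at 3 ages, P2, P6 and P10. Each of the 6 groups stood for 3 labelled libraries, combined by the authors into 1 value per gene. Estimated fragments per group ranged from 6881671 to 7386338, and 18031 to 19336 gene loci reached FPKM 1 or more in a group. The 10 most abundant loci took 7.68% of the fragments in the control group at P2 and 14.4% in the SMA group at P6. Errors below are standard errors of log2 ratios derived from the authors' interval, since no replicate values were held. Errors of differences across ages are the exception. They come from the limma fit, which treats the 3 ages as replicates and does not use the interval. The sizes of these errors cannot be compared with those from the interval.

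The first question was whether the SMA groups lacked Smn1, the mouse gene for the survival motor neuron protein, which is absent by design in affected pups. Control cords had Smn1 at FPKM 2.70 at P2, 4.46 at P6 and 3.54 at P10. In SMA cords Smn1 was FPKM 0.0210 at P2 and was listed at 0 at P6, against 25.6 and 30.0 estimated fragments in the controls. With a floor of 3 fragments in the group, Smn1 was at least 8.52-fold lower in SMA at P2 and at least 10-fold lower at P6. These folds take the control estimate without its own error, so they are not confidence bounds. In the group labelled SMA at P10, Smn1 was FPKM 2.82, or 79.8% of the control value, with 20.2 estimated fragments against 25.9. Smn1 (ENSMUSG00000021645.16) lies on chromosome 13 from 100124852 to 100137690 on the plus strand of GRCm38. The difference at P10 was a log2 ratio of -0.33 ± 1.28 and was not detectable at this depth. Every comparison that uses the SMA group at P10 therefore rests on a group whose Smn1 level was near that of the controls.

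At P2, myelin genes were higher in the group labelled SMA than in controls. A library exchanged between the SMA groups of P2 and P10 stays open, as described below. The difference can therefore not be credited to the genotype alone. Ermn, which encodes a cytoskeletal protein of oligodendrocytes, rose from FPKM 0.438 in control to 8.09 in SMA, a log2 ratio of 4.21 ± 0.79 (adjusted p = 0.000171). Mal, a lipid raft protein of myelin, rose from FPKM 5.62 to 78.6 (log2 ratio 3.81 ± 0.67, adjusted p = 2.86e-05). Sec14l5 rose by 3.93 ± 0.81 on the log2 scale, Gsn, the actin-severing protein gelsolin, by 3.46 ± 0.74, and Mag, a myelin adhesion molecule, by 3.71 ± 0.92 (adjusted p = 0.0483). Of 19114 genes tested, 24 were called, 19 higher and 5 lower in SMA. By the z test from the deposited counts 20 were called, 20 higher and 0 lower, and by intervals that do not overlap 44. The 10 protein-coding genes among them were all higher and, besides these 5, were Nipal4, Fa2h, Ugt8a, Cldn11 and Tmem88b, the last 3 named after their values were seen. Ugt8a and Fa2h make galactolipids of myelin, and Cldn11 forms its tight junctions. Of 23 measured members of the mature oligodendrocyte and myelin list, 23 had higher values in SMA at P2, 6 were called over all genes and 19 adjusted over the list alone. Their median log2 difference was 1.97, above all random lists. Mbp, the major myelin protein gene, had FPKM 1840 in SMA and 150 in control, and its wide interval left it uncalled (log2 ratio 3.62 ± 1.81). Ermn lies on chromosome 2 from 58045113 to 58052864, Mag on chromosome 7 from 30899176 to 30914873 and Mal on chromosome 2 from 127633226 to 127656695. No protein-coding gene was called lower; those with the smallest p were Hoxc12 (log2 ratio -1.15), the Y-linked Ddx3y (-1.40) and Eif2s3y (-1.64), the motor neuron gene Chodl (-0.78) and Ptgds (-0.74). Limited to protein-coding and long noncoding loci, a choice made after seeing the data, 6 genes were called. With the interval also read as that of 1 library, 90 were called, 88 higher and 2 lower.

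At P6, few genes were called between SMA and control cords, and none of the called genes was protein-coding. On data simulated with noise as wide as the interval, the z test at P6 recovered 2% of genes changed 2-fold and 42% of those changed 4-fold. The real z values were narrower, so these shares need not hold for the real data. The wide interval still means that few calls do not mean few differences. Of 19631 genes tested, 9 were called, 4 higher and 5 lower, but by the z test from the deposited counts 0 were called (8 at an unadjusted p under 0.05), and by intervals that do not overlap 23. The only called gene with a name under the rule was Dancr, a long noncoding RNA that hosts small nucleolar RNAs on chromosome 5 from 74093060 to 74095406, with FPKM 97.2 in control and 50.4 in SMA (log2 ratio -0.95 ± 0.09, adjusted p = 5.05e-24). From the counts the same ratio was 0.33 and not called, so the direction of Dancr depended on which deposited value was used. At P2 its FPKM was higher in SMA, at 384 against 105 in control (log2 ratio 1.86 ± 1.85, not called). The small p of Dancr at P6 thus rests on narrow deposited intervals, with an error of 0.09 against 1.85 at P2, and not on replicate values. The other 8 were 5 small RNA loci and 3 loci without a symbol. Genes with the smallest p in the higher direction, none called, were Ucp1, the uncoupling protein of brown fat, at FPKM 1.05 in control and 8.45 in SMA, the adipocyte gene Fabp4 at 1.47 and 10.6, Cox8b at 0.327 and 4.65, the sensory neuron sodium channel Scn11a at 0.368 and 1.17, and the metallothionein Mt2 at 64.7 and 128.

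At P10, the myelin genes lay on the other side: 0 of 23 members of the list had a higher value in the group labelled SMA, and the list's median log2 difference was -0.65, below all random lists. Mbp was FPKM 4281 in control and 2294 in SMA, Mag 315 and 172, and Gfap, the intermediate filament of astrocytes, 318 and 204; none of these was called. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, had FPKM 3.69 in control and 9.41 in SMA (log2 ratio 1.35 ± 0.55, not called). Of 20157 genes tested, 8 were called, 5 higher and 3 lower, and none was protein-coding. By the z test from the deposited counts 0 were called (29 at an unadjusted p under 0.05), and by intervals that do not overlap 16. Among the 8 were Dancr (log2 ratio -1.81 ± 0.14, adjusted p = 1.32e-35, against 1.86 at P2) and, named after its value was seen, Rnu12, the U12 RNA of the minor spliceosome (FPKM 49.7 in control and 7.79 in SMA, log2 ratio -2.67 ± 0.42, adjusted p = 5.29e-07). From the counts, Dancr had a ratio of 0.16 and Rnu12 -2.77. Higher genes with the smallest p, none called, included Vaultrc5 and, besides Cdkn1a, the adhesion gene Cxadr, Hn1 and Shtn1; Cxadr was FPKM 14.7 in control and 36.8 in SMA.

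**Figure D1:**
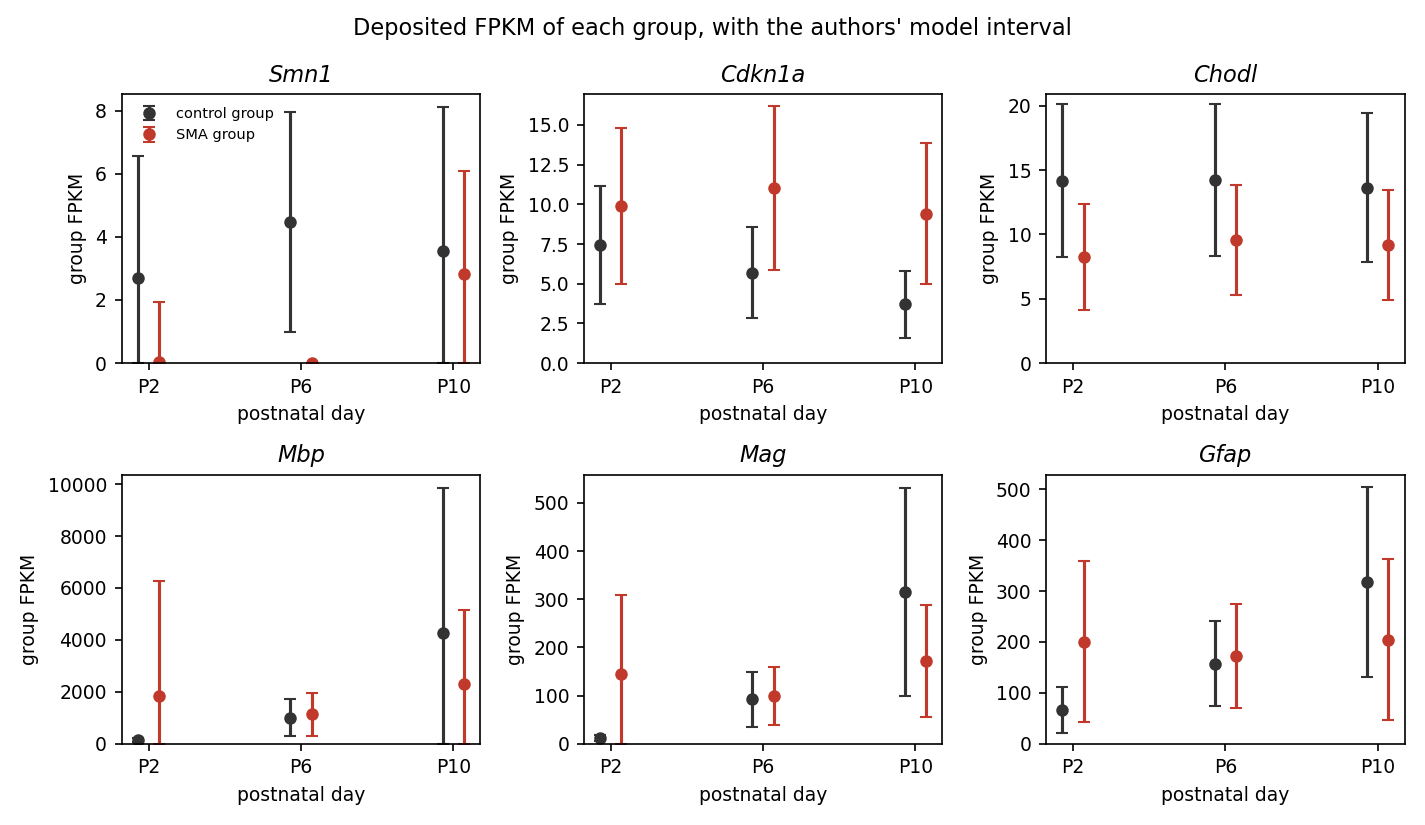
Group FPKM (vertical axis) of Smn1, Cdkn1a, Chodl, Mbp, Mag and Gfap by postnatal day (horizontal axis), with 1 point per group, control in dark grey and SMA in red, and bars for the authors' model interval. Smn1 was FPKM 0.0210 in SMA at P2, listed at 0 at P6 and 2.82 at P10, and Mbp, Mag and Gfap were higher in SMA at P2 and lower at P10, with only Mag at P2 called.

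The next question was which genes differed the same way at every age. Cdkn1a was higher in SMA at 3 of 3 ages, by 0.79 ± 0.16 on the log2 scale across ages, and Ccng1, another p53 target, by 0.46 ± 0.09. Chodl, a surface protein of fast motor neurons, was lower at 3 of 3 ages, by -0.59 ± 0.09, with FPKM 14.2 in control and 8.24 in SMA at P2. None of these passed the adjustment (adjusted p = 0.999 for each, limma). Of 21960 genes tested, 1 was called by limma, the predicted small RNA Gm23604, named after its value was seen (log2 difference -3.95, adjusted p = 0.035), and 451 had an unadjusted p under 0.05, 247 higher and 204 lower. The other genes with the smallest p were Lars2 (1.03), Uspl1 (0.48) and Dcxr (0.67) on the higher side, and on the lower side the alpha globin gene Hba-a1 (-0.58), the histone genes Hist1h2bn (-0.47) and Hist1h2al (-0.68), and 1 of several loci with the symbol Rcbtb2 (-0.69). Without the P10 groups limma called no gene, with 1198 at an unadjusted p under 0.05; without P2 the calls were 5 and without P6 they were 8. Chat, the acetylcholine-synthesizing enzyme of motor neurons, had log2 ratios of 0.26 at P2, -0.14 at P6 and -0.67 at P10. Mki67, a proliferation marker, differed by -0.21 across ages, and Snap25, a synaptic protein, by 0.08. The APC/C activators Fzr1 and Cdc20, in the ubiquitin ligase named in the study's title, differed by -0.01 and -0.19; none of these was called.

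Gene groups were compared with all other genes across the 3 ages, and 11 of 38 lists were called by camera with its preset correlation; with an estimated correlation no list was called (0 of 38 at an adjusted p under 0.05, smallest unadjusted p = 0.0382, for motor neuron markers), and fry called none. The p53 targets were higher in SMA, with medians of 0.18 at P2, 0.28 at P6 and 0.05 at P10 and 13 of 28 members higher at all 3 ages (camera adjusted p = 7.21e-09, and adjusted p = 0.968 with an estimated correlation). Cdkn1a, Ccng1, Pmaip1 (0.52), Eda2r (0.39) and Trp53inp1 (0.37) had unadjusted p under 0.05, while the abundant Ei24 differed by 0.14. Glucocorticoid and fasting response genes had medians of 0.52, 0.39 and -0.20 at P2, P6 and P10 (adjusted p = 7.88e-09, and 0.968 with an estimated correlation); Mt2 was FPKM 57.9 in control and 146 in SMA at P2, and Mt1 71.5 and 156. Replication-dependent histones were lower, with medians of -0.21 at P2, -0.21 at P6 and 0.03 at P10 (adjusted p = 4.56e-09, and 0.968 with an estimated correlation); Hist1h4d and Hist1h4h differed by -0.16 and -0.03 across ages. These 3 lists kept their call and direction when each age was left out in turn. Cell cycle genes were lower, with medians of -0.25, -0.13 and 0.05 (adjusted p = 1.03e-05, 0.968 with an estimated correlation, and 0.0761 without P2); Pcna differed by -0.07 and Tyms by -0.06.

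Motor neuron markers were lower in SMA, with medians of -0.08 at P2, 0.03 at P6 and -0.22 at P10 (camera adjusted p = 4.83e-05, 0.968 with an estimated correlation, and 0.103 without P10). Besides Chodl, the neuropeptide gene Calcb (-0.40) and the choline transporter Slc5a7 (-0.25) had unadjusted p under 0.05, and 1 member was called adjusted over the list alone; Prph and Sv2b differed by -0.22 and 0.10. Neurofilament and axon genes had medians of -0.13, 0.10 and -0.09 (Uchl1 0.11 and Nefl -0.15 across ages), excitatory neuron markers -0.24, 0.18 and 0.06 (Sst 0.08, Slc17a6 0.12) and inhibitory neuron markers -0.05, 0.00 and 0.13 (Gad1 0.08). Synaptic vesicle genes had medians of 0.09, 0.10 and -0.10, and channel genes 0.25, 0.06 and -0.24, with Scn2a1 at 0.20 and Scn1a at 0.07 across ages; apart from the motor neuron markers, none of these lists was called.

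Medians of most glial and vascular lists were above 0 at P2 and below 0 at P10; the change between ages was tested for single genes and not for lists. Apart from the myelin and astrocyte lists, none of these lists was called across ages. The myelin list was called higher across ages (adjusted p = 0.000236, 0.968 with an estimated correlation), and without P2 it was called lower (adjusted p = 3e-06). Astrocyte markers had medians of 0.80, 0.13 and -0.28 (adjusted p = 0.0248, 0.968 with an estimated correlation, and 0.0677 in the lower direction without P2); Gfap was FPKM 65.6 in control and 201 in SMA at P2, while Fabp7, a gene of immature astrocytes, was 383 and 259, and Aldoc 153 and 204. Oligodendrocyte precursor markers had medians of 0.49, -0.01 and -0.32, with Gpr17 at FPKM 14.0 and 31.4 at P2 and Ptprz1 at 61.9 and 60.1. Endothelial markers had medians of 0.31, -0.06 and -0.36 (Cldn5 -0.21 and Mfsd2a 0.27 across ages), and pericyte markers 0.21, 0.02 and -0.35 (Rgs5 0.04, Vtn -0.22). Cholesterol synthesis genes followed with 0.36, 0.07 and -0.37; Hmgcs1 was FPKM 131 in control and 184 in SMA at P2, and 294 and 214 at P10, and Cyp51 differed by -0.03 across ages. Microglia markers had medians of 0.24, -0.01 and 0.04 (P2ry12 0.10), complement genes 0.20, 0.13 and -0.02 with C1qa at 0.41 and C1qc at 0.25 across ages, reactive astrocyte genes 0.02, 0.13 and -0.13 (Vim -0.03, H2-D1 0.17) and interferon response genes 0.07, -0.01 and -0.29 (Ifi27 0.26, Ifit2 0.09).

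Of the markers of tissue around the cord, of its lining and of blood, the fibroblast and meningeal, erythroid and skeletal muscle lists were called with the preset correlation only, and the Schwann cell, dorsal root ganglion, bone and cartilage and ependymal lists were not called. Fibroblast and meningeal markers had medians of -0.13, 0.23 and -0.55 (lower, adjusted p = 0.000268, 0.968 with an estimated correlation, and higher at 0.69 without P10); Col1a2 was FPKM 55.9 in control and 34.8 in SMA at P10, and Igf2 54.8 and 36.7. Schwann cell markers had 0.23, 0.25 and -0.55, with Pmp22 at FPKM 93.4 in control and 48.8 in SMA at P10. Erythroid genes were lower with -0.14, -0.14 and -0.26 (adjusted p = 0.000273, 0.968 with an estimated correlation, and 0.127 without P10); Hba-a1 and Hbb-bs (-0.45) were the 2 members called adjusted over the list alone. Skeletal muscle markers had 0.48, 0.06 and 0.05 (higher, adjusted p = 0.0396, 0.968 with an estimated correlation, and lower at 0.747 without P2); Acta1 was FPKM 5.67 and 8.45 at P2, and Pvalb, which spinal neurons also express, 0.576 and 3.34. Dorsal root ganglion markers had -0.05, 0.39 and -0.08 (Nefh 0.04, Tac1 -0.06), bone and cartilage markers 0.28, 0.06 and -0.24 (Col11a1 -0.03, Sox5 0.04) and ependymal markers -0.20, 0.02 and 0.02 (Foxj1 -0.02, Dnah9 -0.06).

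Among the remaining lists, only nuclear oxidative phosphorylation genes were called; they were higher, with medians of 0.13, 0.15 and -0.08 (adjusted p = 0.0156, 0.968 with an estimated correlation, 0.495 without P2 and 0.649 without P6); Atp5b differed by 0.08 and Cox6c by 0.03. The SMN complex and Sm core had medians of 0.00, 0.17 and 0.07, with Snrpe at 0.15 and Strap at 0.12 across ages. APC/C subunits and regulators had -0.10, 0.02 and 0.04 (Anapc5 0.06, Ube2s -0.06), and the minor spliceosome 0.07, 0.15 and -0.04, where Rnu12 was the only member called, at P10. Ribosomal protein genes had -0.03, 0.10 and 0.11 (Rps12 -0.03, Rps27 0.14), integrated stress response genes 0.13, 0.20 and -0.07 (Psat1 0.09, Slc3a2 0.10) and unfolded protein response genes 0.05, 0.18 and -0.10 (Canx 0.08, Calr -0.01). Immediate early genes had 0.00, 0.08 and -0.21 (Jun -0.08, Fos 0.17), insulin-like growth factor genes 0.05, 0.13 and -0.24 (Igfbp2 -0.14), circadian genes 0.21, 0.21 and -0.18 (Tef 0.16, Nr1d2 0.06) and apoptosis genes 0.02, 0.09 and 0.01 (Trp53bp1 0.07, Mcl1 0.05). The single measured mitochondrially encoded gene, mt-Nd6, differed by -0.08.

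**Figure D2:**
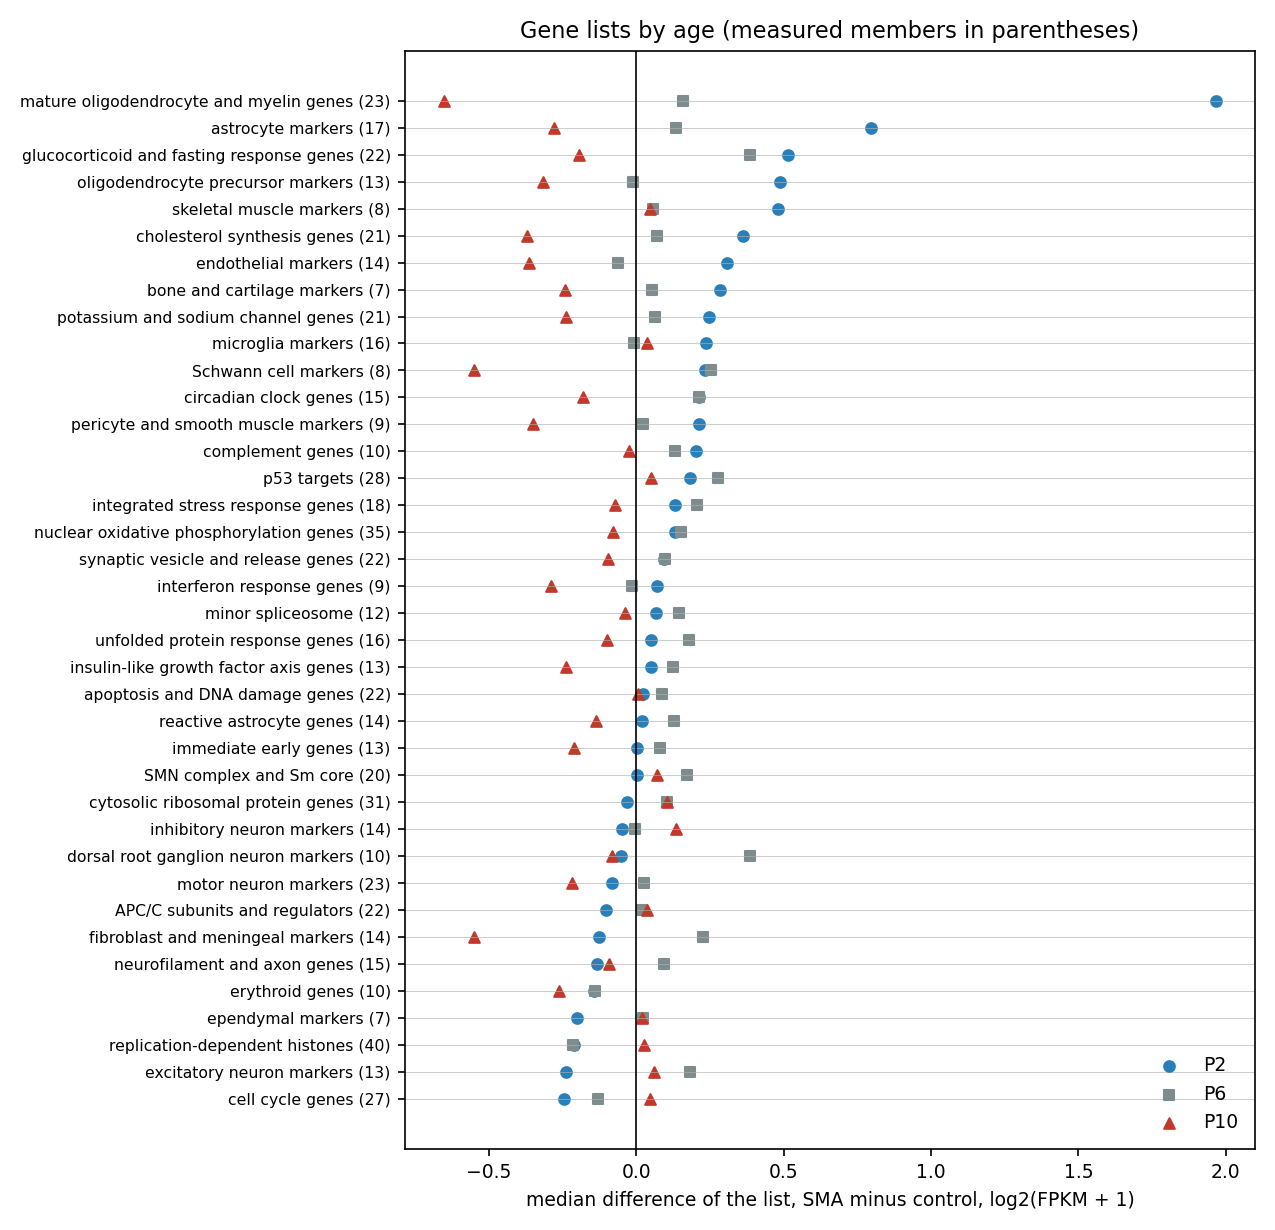
Median difference of each gene list between SMA and control on the log2(FPKM + 1) scale (horizontal axis) for 38 lists (vertical axis), with 1 marker per age, blue circles for P2, grey squares for P6 and red triangles for P10. The myelin list spans from -0.65 at P10 to 1.97 at P2, and the p53 targets lie at 0.18, 0.28 and 0.05.

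Postnatal development set the scale for these differences. In control cords, myelin genes rose steeply from P2 to P10: Opalin by 6.23 ± 1.48 on the log2 scale, Ermn by 5.60 ± 0.71 and Nipal4 by 4.88 ± 0.72. Among the genes that fell were Islr2 by -2.44 ± 0.59, Cxadr by -2.40 ± 0.44, the phosphatase gene Dusp4 by -2.38 ± 0.50, Mex3a by -2.05 ± 0.48 and the transcription factor gene Neurod6 by -2.02 ± 0.56. Of 19956 genes tested in control, 126 were called, 109 higher and 17 lower at P10, with 100 of them protein-coding and 20 of 23 measured myelin genes among them. From the deposited counts 216 were called, by intervals that do not overlap 272, and in protein-coding and long noncoding loci with the interval read as that of 1 library, a choice made after seeing the data, 767. In SMA, 12 of 19938 genes were called between the groups labelled P2 and P10, 7 higher and 5 lower, and 0 of the myelin genes (66 genes had an unadjusted p under 0.05 by the z test). For the same settings 2, 22 and 5 were called. The only protein-coding call there was Ucp1, which fell by 5.60 on the log2 scale, from FPKM 7.70 to 0.159 (adjusted p = 0.00875). Mbp was FPKM 1840 in SMA at P2 and 2294 at P10, against 150 and 4281 in control.

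The difference between SMA and control itself changed from P2 to P10 in 12 of 20916 genes, 2 in the higher and 10 in the lower direction. From the deposited counts 23 were called, 0 higher and 23 lower, and at FPKM 5 the calls were 20. In protein-coding and long noncoding loci with the interval read as that of 1 library, a choice made after seeing the data, 142 were called, 7 higher and 135 lower. Ermn changed by -4.91 ± 0.93 on the log2 scale (adjusted p = 0.000561), Sec14l5 by -4.79 ± 0.96, Mal by -4.48 ± 0.84 and Nipal4 by -4.40 ± 0.97. The lower direction held 9 protein-coding genes and the higher none; those with the smallest p on the higher side, not called, were Cxadr (1.82 ± 0.69), Hn1 (1.46), Shtn1 (1.32), the homeobox gene Hoxc12 (1.57) and Kcnh4 (2.54).

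The genotype difference at P10 was also set against development up to P6, to ask whether cords labelled SMA at P10 lay towards a younger profile. Of the 19 genes called between P2 and P6 in control and measured at P10, 17 had risen, and 12 of these 17 were lower in SMA at P10, with a median of -0.67. Across these genes Spearman's rho was -0.31 and Pearson's r -0.04. Random gene sets matched on expression had a median rho of -0.51, so the relation was not particular to the chosen genes (random set p = 0.817). The random sets carry the relation themselves, so this p does not answer whether the profile was younger. Over 8122 protein-coding genes at FPKM 5 or more, chosen after seeing the data, rho was -0.554 and r -0.597, towards a younger profile. Over 294 genes changed at least 2-fold, rho was -0.127. Genes are not independent replicates, and this describes these groups only. Across 21960 genes, the differences at P2 and P10 had a rho of -0.41 and an r of -0.18, those at P2 and P6 0.17 and 0.08, and those at P6 and P10 -0.09 and 0.01; these are 3 relations, given without a p.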

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

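The tests of developmental position, of transgene reads and of the p53 targets, the count over splits and the other thresholds of the test for control libraries were chosen after the results were seen; the test of the change of the difference was planned, and the test for control libraries was written before its value was seen. The difference between SMA and control changed from P2 to P10 in 12 genes, by a test of the change itself. Among them, on the log2 scale, were Ermn (-4.91), Sec14l5 (-4.79), Mal (-4.48), Nipal4 (-4.40), Gsn (-4.36), Fa2h (-3.94), Cldn11 (-3.64) and the sodium channel subunit Scn4b (-3.63).

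The SMA group at P2 looked older, and the group labelled SMA at P10 younger, than its controls, in genes that changed at least 2-fold from P2 to P10 in control. On a scale from control P2 to control P10, SMA at P2 was displaced towards P10 by 0.42 for 363 rising genes (quartiles 0.354 and 0.492) and 0.355 for 120 falling genes, and SMA at P10 towards P2 by 0.459 (quartiles 0.377 and 0.538) and 0.335, while SMA at P6 lay within 0.0717 of control P6. The choice of genes on these control values gave at most 0.122 in simulations with no change, and genes chosen at 1.5-fold without the control group compared were displaced by 0.429 and 0.354 at P2 and 0.452 and 0.307 at P10, though at 2-fold the 9 falling genes left for P10 had -0.0271. Falling genes, none of which was on the myelin, cell cycle or erythroid lists, were displaced at P2 by 0.355. When chosen without control P2 they were displaced by 0.354. A greater share of oligodendrocytes at P2 was predicted to leave falling genes near control P2, which was not met. FPKM is scaled to the depth, so more RNA of oligodendrocytes could lower the values of other genes. The median log2 ratio of the 19114 genes tested at P2 was -0.00585, so no lowering of genes in general was seen. This argues against scaling as the source of the displacement of falling genes at P2. Lowering limited to genes of other cell types was not tested, so a greater share of oligodendrocytes is not excluded. A library exchanged between SMA P2 and SMA P10, which would place both groups about 0.333 of the way, stays open: the farthest displacement lay 0.126 from that value, under a bound of 0.17 set after the pattern was seen, but 0.333 lay outside the quartiles of the rising genes, and maturation altered by the genotype, limited to P2 and P10, was not excluded by any value either. The deposited intervals of 71 rising genes, relative to other genes at the same FPKM, were widest in SMA P2, at 1.265. The other groups lay at 0.9415 to 1.067. For 120 falling genes SMA P2 had 1.031, within the 0.9919 to 1.043 of the other groups. The widths of the intervals therefore do not decide between these explanations.

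The Smn1 level of the group labelled SMA at P10 was near that of the controls. Reads of the human transgenes assigned to Smn1 are argued against by the SMA groups at P2 and P6, which carry the same transgenes and together had 0.202 estimated fragments against 20.2, unless the 0 at P6 is a failed estimate. If control libraries sat in the P10 group, genes that differed alike at P2 and P6, by at least 0.4 on the log2 scale and with a change under 0.5 from P2 to P10 in control, would keep under 0.3 of their P6 difference at P10; the median share of 20 such genes was -0.0963 (quartiles -0.291 and 0.188), which met the prediction, and it was -0.237 with a threshold of 0.25, -0.345 without the filter on the change in control and -0.599 with both. A comparison added after that value was seen showed that the same step kept 0.0292 of the difference at P2 in 8 genes alike at P6 and P10, and 0.301 at P6 in 9 genes alike at P2 and P10, with lower shares at both ages under the other thresholds, so little is kept at any age and the step cannot tell a mixed group from a difference that varies with age. Control libraries in that group stay open, and 8 of the 20 genes had the same direction at P10 as at P6. Among these 8 were Chodl (-0.53 at P6 and -0.53 at P10 on the scale of that test) and Ccng1 (0.54 and 0.37), neither called. Cdkn1a, not one of the 20 and not called, also kept its direction (log2 ratios of 0.42, 0.95 and 1.35 at P2, P6 and P10). Chodl, Ccng1 and Cdkn1a were all among the genes with the smallest p across ages, in a fit that includes P10, so they cannot decide the question. An exchange with SMA libraries of P2 would bring almost no Smn1.

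The p53 targets were called higher in SMA across ages by camera with its preset correlation only. At P10 their median was 0.05, within the random lists (percentile 79.2). A difference in maturity between the groups is argued against by P6, where SMA and control lay at about the same developmental position and the list's median was 0.279, above all random lists. A different sex mix is argued against too: Y-linked Ddx3y was FPKM 17.9 in control and 6.82 in SMA at P2 but 4.92 and 14.9 at P6, while the list was above 0 at both ages, with 0.183 at P2. A response to the loss of SMN, named by the design, may explain the pattern and stays a hypothesis, since the call was lost with an estimated correlation (adjusted p = 0.968). Other effects of illness stay open: the glucocorticoid and fasting response list, which shares Cdkn1a, was higher at the same ages, with medians of 0.52 at P2 and 0.39 at P6 (camera adjusted p = 7.88e-09, and 0.968 with an estimated correlation).

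Across ages, limma called 1 gene with the real grouping, and the highest other of the 10 splits of the 6 group values into 3 and 3 gave 56. The 10 splits are too few for a share under 0.05. With age in the fit, 6 of them are 3 fits counted double, each of which rests on the SMA against control difference at 1 age, with 38 calls for P2, 35 for P6 and 56 for P10. The 3 other splits estimated from all ages, as the real one is, gave 3, 0 and 0 calls. That 8 splits gave at least 1 call therefore says nothing about chance.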

How the results depend on the processing

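The results limited to protein-coding and long noncoding loci, with a narrower interval, with P2 and P10 averaged, the relations over 8122 protein-coding genes or with 2 choices combined, and the other choices of genes in the tests of control libraries and of developmental position were chosen after seeing the data. Of 670 values of named genes under the z test from counts and under re-centring, 667 kept their side of the threshold, though 35 of these, called in neither setting, turned sign, from at most 0.117 in size to at most 0.329. Most of the 670 values were of genes not called in the first place, which could hardly cross the threshold, so the share kept says little. Dancr turned to 0.334 at P6 and 0.158 at P10 with the counts, and Rnu12 at P10 lost its call. These were the only calls of named genes at P6 and P10, so none was kept there with the counts. Of 78 counts and relations, 40 stayed near the first value, within 1.5 times for counts and within a set distance of rho for relations. With the z test from counts, calls were 0 at P6, 0 at P10, 216 for P10 against P2 in control, 2 in SMA and 23 for the change of the difference. With intervals that do not overlap as the rule, they were 44 at P2, 23 at P6, 16 at P10, 272 in control and 22 in SMA. At FPKM 5 the change of the difference had 20 calls. Limited to protein-coding and long noncoding loci, calls were 6 at P2, 1 at P6, 1 at P10 and 0 for P10 against P2 in SMA; with the interval also read as that of 1 library they were 90, 5 and 2 at P2, P6 and P10, 767 in control, 5 in SMA and 142 for the change of the difference. Across ages, limma called 0 with a pseudocount of 5, with no filter, at FPKM 5, with quantile normalization, with no trend, without P10 and in protein-coding and long noncoding loci (173 to 1319 at an unadjusted p under 0.05), 5 without P2, 8 without P6 and 10 with P2 and P10 averaged; the 10 to 13 lists called by camera under the other settings became 0 with an estimated correlation. The maturation relation was -0.127 with genes changed 2-fold, -0.049 without the myelin, cell cycle and erythroid lists, -0.083 with both and -0.554 over 8122 protein-coding genes; the relation of the P2 difference with the control change from P6 to P10 was 0.372 and became 0.681 over those genes, and the P2 with P10 correlation was -0.57 at FPKM 5. Fewer genes tested or a narrower interval change calls by construction; otherwise the cause was not tested. No paired analysis was possible because the tables hold 1 value per group. Planned edgeR, DESeq2, replicate block and leave-one-out settings could not be run for the same reason. The width of the interval limits what a single age can show: on data simulated with noise as wide as the interval, 0% to 4% of 2-fold changes were recovered. The real z values were narrower, so this share need not hold for the real data.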

Other observations

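Ucp1, Fabp4 and Cox8b were named for a small p at P6, were on no list and were not called between SMA and control at P2 or P6. Of the genes in this part, Prodh, S100a8, S100a9, Agt, Uty, Kdm5d, Gm42418 and Rn18s-rs5 were chosen after their values were seen. Ucp1 was FPKM 3.66 in control and 7.70 in SMA at P2, and 1.05 and 8.45 at P6, but 0.251 and 0.159 at P10. Fabp4 was 3.64 and 7.46 at P2 and 1.47 and 10.6 at P6, and Cox8b 2.06 and 4.71 at P2 and 0.327 and 4.65 at P6. The metabolic gene Prodh had log2 ratios of 1.26 at P2, 1.32 at P6 and 0.26 at P10. The neutrophil genes S100a8 and S100a9 differed by 0.37 and 0.43 across ages, and the angiotensinogen gene Agt, also an astrocyte marker, by 0.66, none of them called.

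Y-linked genes differed between groups without following genotype or age. Ddx3y was FPKM 17.9, 4.92 and 13.1 in control and 6.82, 14.9 and 6.63 in SMA at P2, P6 and P10; Eif2s3y had log2 ratios of -1.64, 1.11 and -0.79, and Uty and Kdm5d were likewise highest in control at P2. Lars2 was FPKM 1290, 1691 and 2196 in control and 1931, 5070 and 4189 in SMA, and Gm42418, a locus that overlaps ribosomal RNA sequence, 764, 1104 and 1065 against 986, 1927 and 1726, while Rn18s-rs5 had log2 ratios of 0.30, -0.08 and -0.05. Vaultrc5 was listed at 0 in SMA at P2 and P6, with FPKM 8.90 and 6.26 in control, and had 14.0 in SMA and 6.43 in control at P10.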
